A study of Rattus norvegicus with 24 samples.

How the data were processed

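Gene expression was measured in rat INS-1E insulinoma cells on 24 single-colour Affymetrix arrays, 3 for each of 8 groups that combine cytokines or none, BRD0476 or DMSO, and 6 or 12 h. Per the labels, the deposited intensity values were made with RMA, which corrects background, normalizes across arrays and summarizes the probes of a probe set. The RMA version, the chip definition and the step back from log2 to linear values are not stated. The table holds 31099 probe sets, 57 of them controls. The values are linear and positive and reach 24852.9, with array medians between 5.49 and 5.57 on the log2 scale, and they were taken to log2 without further normalization. Arrays of the same group correlated with r between 0.992 and 0.999.

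The annotation table used here names 21268 probe sets, 20832 of them with 1 gene symbol and 436 with several. The other 9831, controls included, carry no name. After controls were set aside, 20826 named probe sets gave 14217 genes. No genome sequence was used, so genes are identified through the annotation alone. Where a gene had several probe sets (4525 genes), the probe set with the highest mean over all arrays stood for it, and the text says where other probe sets of a named gene moved the other way. Among genes called with cytokines at 6 h that have several probe sets, 225 of 2614 also had a probe set called the other way. Symbols were checked against Entrez records, which renamed 0 genes and left 50 without a current record. A gene of interest without a named probe set is called not named in the annotation used here.

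Differences were fitted with limma 3.58.1 in R 4.3.3 on log2 values, with a mean for each of the 8 groups, 16 residual degrees of freedom and 3.97 prior degrees of freedom from eBayes. The p-values were adjusted with Benjamini and Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The median standard error of a log2 change was 0.102. With 3 arrays against 3, an exact test cannot give a two-sided p under 0.1, so the calls rest on the model. The 13 comparisons were cytokines against none within each vehicle and time, BRD0476 against DMSO within each cytokine condition and time, the interaction of both at each time, the change with time of the cytokine effect in DMSO and of the BRD0476 effect with cytokines, and 12 h against 6 h in untreated cells.

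Groups, comparisons, gene lists and most alternatives were fixed before the data were examined. The 26 lists held 817 members, of which 726 were measured, 679 distinct genes with 38 in more than 1 list. They cover interferon-gamma targets, NF-κB targets, chemokines, antigen processing, JAK-STAT components, IL-1 and TNF receptor components, nitric oxide and arginine metabolism, beta-cell identity, exocytosis, the unfolded protein response, apoptosis, p53 targets, antioxidant genes, cholesterol, fatty acids, glycolysis, the respiratory chain, the cell cycle, xenobiotic targets, immediate early genes, ubiquitin and the proteasome, and markers of 5 other cell kinds. Each list was tested with camera at a preset correlation of 0.01, with Benjamini and Hochberg over the 26 lists of a comparison. Counts are given over all genes and with p adjusted over the list alone. Of 120 list results called, 1 had another sign of the median when arrays were centred on their medians or quantile normalized.

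Genes were named by a rule. For each comparison these were the 8 largest rises and the 8 largest falls among called genes whose 3 arrays all lay beyond the other 3 (for interactions, among called genes), up to 4 called members of each list with the largest change or up to 2 where none was called, and a panel that included Nos2, Cxcl10, Irf1, Socs1, Nfkbia, Icam1, Sod2, Ins1, Ins2, Pdx1, Mafa, Slc2a2, Hspa5, Ddit3, Jak2 and Usp9x. A gene named in a comparison may be given in another. The share of the cytokine response left with BRD0476 is the slope through the origin of the cytokine change with BRD0476 on that with DMSO, over genes called at the other time point with a change of at least 1, so that selection and slope use different arrays.

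The steps were tested on simulated data made from the spread of the real arrays. Simulated genes varied independently and few of them changed, unlike in the real arrays, so this tests the steps and not the calls. Of 50 genes at each size, the fit recovered 11 at a log2 change of 0.25, 30 at 0.5, 50 at 1 and 50 at 2, with 10 false calls among 151. A share simulated at 0.5 came back as 0.496 at 6 h and 0.495 at 12 h, and a list shifted by a known amount had the smallest camera p.

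Alternatives were array weights, a fit with only the arrays compared, replicate number as a block, an intensity trend and robust prior, the mean of a gene's probe sets, every probe set, 4440 dim genes left out, centred arrays, quantile normalization, and leaving out each array in turn. For lists they were camera with an estimated correlation, fry, the replicate block and the mean of probe sets. After the values were seen, a fit without both replicate 3 arrays of the cytokine and DMSO groups was added, as were lists of clock genes and of arms of the unfolded protein response. No array was left out of the fit that the report gives.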

Results

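Rat INS-1E insulinoma cells, a beta-cell line that makes insulin, were profiled on 24 Affymetrix expression arrays. Cells were left without cytokines or received a cocktail of interferon-gamma at 50 ng/ml, TNF-alpha at 25 ng/ml and IL-1beta at 10 ng/ml. Each condition was combined with the vehicle DMSO or with 10 uM of the compound BRD0476, for 6 or 12 h, which gives 8 groups of 3 arrays. Interferon-gamma signals through JAK kinases and STAT factors, whereas IL-1beta and TNF-alpha act mainly through NF-κB and MAP kinases, and the cocktail is widely used as a model of immune attack on beta cells. Cytokine treatment was the main source of variation: the first principal component held 65.2% of the variance and the next held 10.2%.

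Changes are differences of mean log2 intensity, given with ± their standard error. Adjusted p-values come from limma over 14217 genes, with n = 3 arrays per group. Unless the text says otherwise, every gene said to rise or fall had all 3 arrays of a group beyond all 3 of the other. That pattern arises in 10% of genes by chance alone. Gene lists fixed before the data were examined carry counts of genes up and down, the median change, and the adjusted p of limma camera with a preset correlation of 0.01. Where a list's call is lost when camera estimates the correlation between genes from these arrays, that adjusted p is given too, and all other list calls hold with it. The values come without detection calls, so a change to or from a level near the lower quartile of all values (3.84) is best read as a lower bound, and the order of such changes is not certain. The p-values measure only the spread between these arrays, and 3 per group limits the precision of every estimate.

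With 6 h of cytokines in DMSO, INS-1E cells switched on interferon, chemokine and antigen-presentation genes and the NF-κB programme, many of them from near background. ER-stress transcription factors and death-related genes rose with them. Genes of cholesterol synthesis, cell division and the respiratory chain fell (for the last, adjusted p = 0.153 with an estimated correlation), and several beta-cell transcription factors dropped while insulin itself barely moved. Of 14217 genes, 7345 changed, 3453 up and 3892 down, and 887 rose and 717 fell by at least 2-fold.

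Many of the largest rises at 6 h were in genes driven by interferon, though LOC100910973 rose further than any gene named here. Cxcl10, the chemokine ligand of CXCR3, rose by 8.81 ± 0.47 (12.82 against 4.01, a level near the lower quartile of all values, adjusted p = 1.4e-12), read by a single probe set. Cd74, the MHC class II invariant chain, rose by 8.61 ± 0.13 and Cxcl9 by 8.07 ± 0.23. The antiviral genes Rsad2 (8.68 ± 0.41) and Mx2 (8.41 ± 0.28) and the GTPase gene Gbp2 (8.54 ± 0.38) moved as far. Irf1, a transcription factor that carries the interferon signal forward, rose by 4.74 ± 0.11, and its partners Stat2 by 4.24 ± 0.13 and Irf9 by 3.79 ± 0.12. Of 41 measured interferon-gamma targets, 40 rose and 0 fell (40 and 0 adjusted over the list alone), with a median of 4.39 and adjusted p = 1.58e-31. Antigen processing followed: Tap1, which pumps peptides into the ER, rose by 5.53 ± 0.09 and the immunoproteasome subunit Psmb8 by 4.72 ± 0.09. In all, 20 of 22 genes of that list rose (20 adjusted over the list alone, median 2.55, adjusted p = 6.76e-17). Among JAK-STAT components, Jak2 rose by 1.78 ± 0.14 and the feedback inhibitor Socs1 by 1.76 ± 0.20, with 19 of 34 up and 4 down (19 and 4 adjusted over the list alone, median 0.29, adjusted p = 0.00132).

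NF-κB targets rose alongside. Icam1, an adhesion molecule, climbed by 6.84 ± 0.18 (adjusted p = 1.7e-17), Cxcl1 by 6.96 ± 0.23, Birc3 by 4.39 ± 0.11 and the pathway's own inhibitor Nfkbia by 2.95 ± 0.08. Of 34 list members, 25 rose and 0 fell (25 and 0 adjusted over the list alone, median 2.10, adjusted p = 2.52e-15). Sod2, the mitochondrial superoxide dismutase, rose by 2.14 ± 0.08. Chemokines and cytokine ligands counted 18 up and 1 down of 29 (18 and 1 adjusted over the list alone, median 1.13, adjusted p = 1.6e-07). IL-1 and TNF receptor components counted 14 up and 5 down of 27 (15 and 6 adjusted over the list alone, median 0.24, adjusted p = 0.00416, and adjusted p = 0.166 with an estimated correlation). Nos2, the inducible nitric oxide synthase, stayed at 5.98 with cytokines against 5.88 without (change 0.10 ± 0.11, adjusted p = 0.496), on the single probe set that carries this gene. Ass1, which recycles citrulline to arginine, did rise, by 3.70 ± 0.23, and the nitric oxide and arginine list had 9 up and 4 down of 19 (9 and 4 adjusted over the list alone, median 0.21, adjusted p = 0.301).

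Stress and death genes moved too. Ddit3, which encodes the stress factor CHOP, rose by 4.24 ± 0.10 (11.82 against 7.59, adjusted p = 5.14e-18), Atf3 by 3.87 ± 0.19 and Trib3 by 3.36 ± 0.12, whereas the ER chaperone gene Hspa5 rose by only 0.36 ± 0.06 (13.43 against 13.06, adjusted p = 1.58e-05). The unfolded-protein-response list had 25 up and 7 down of 43 (25 and 7 adjusted over the list alone, median 0.42, adjusted p = 9.79e-05). Casp4 rose by 4.81 ± 0.12, the death receptor gene Fas by 3.16 ± 0.11 and Tnfsf10, which encodes TRAIL, by 2.94 ± 0.18. Apoptosis genes counted 18 up and 9 down of 39 (18 and 9 adjusted over the list alone, median 0.20, adjusted p = 0.0122). Cdkn1a, the p21 cell-cycle brake, rose by 1.63 ± 0.21 and Gadd45a by 1.86 ± 0.07. Of the list, 12 of 17 p53 targets rose with 4 down (12 and 4 adjusted over the list alone, median 0.82, adjusted p = 0.00168).

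Cell-cycle and metabolic genes fell at 6 h. In cholesterol synthesis, 18 of 20 genes fell and 0 rose (18 and 0 adjusted over the list alone, median −0.80, adjusted p = 1.37e-08), among them Stard4 at −1.52 ± 0.09, Acat2 at −1.47 ± 0.10 and Sqle at −1.22 ± 0.06. Cell-cycle genes counted 33 down and 4 up of 43 (33 and 4 adjusted over the list alone, median −0.63, adjusted p = 4.02e-09), with Cdkn2c at −1.98 ± 0.07, Bub1b at −1.64 ± 0.07 and Cdc20 at −1.57 ± 0.09. Respiratory-chain genes fell by small amounts in 35 of 43 members with 1 up (35 and 1 adjusted over the list alone, median −0.34, adjusted p = 1.05e-06, and adjusted p = 0.153 with an estimated correlation), for example Ndufa4 at −0.85 ± 0.05. Fatty-acid genes counted 10 down and 4 up of 26 (10 and 4 adjusted over the list alone, median −0.16, adjusted p = 0.0522), with Elovl6 at −2.03 ± 0.10 and Fasn at −1.08 ± 0.09. The sharpest single falls were Nptx1, a secreted synaptic protein gene, at −4.41 ± 0.09 (adjusted p = 3.88e-19), Slc15a2 at −3.16 ± 0.13 and Gpd1 at −3.02 ± 0.09. Usp9x, a deubiquitinase gene, fell by 0.91 ± 0.08 (adjusted p = 1.98e-09).

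Beta-cell identity genes went down in part. Nkx6-1 fell by 1.52 ± 0.11 (7.27 against 8.79, adjusted p = 2.97e-10), Isl1 by 1.17 ± 0.14, Mafa by 0.69 ± 0.07 and Pdx1 by 0.56 ± 0.08. Ins1 held at 14.48 against 14.53 (change −0.05 ± 0.05, adjusted p = 0.458). Ins2 fell by 0.23 ± 0.06 (adjusted p = 0.00307), a call that is lost when only the 6 arrays of this comparison are fitted (adjusted p = 0.0765). The identity list had 18 down and 5 up of 34 (18 and 5 adjusted over the list alone, median −0.20, adjusted p = 0.0508). Other lists were not called as groups at 6 h: exocytosis had 7 up and 11 down of 35 (adjusted p = 0.714), antioxidant genes 11 and 14 of 36 (adjusted p = 0.724), glycolysis 5 and 13 of 28 (adjusted p = 0.237), xenobiotic targets 4 and 1 of 13 (adjusted p = 0.228), immediate early genes 11 and 8 of 32 (adjusted p = 0.216) and ubiquitin and proteasome genes 15 and 8 of 31 (adjusted p = 0.108). Adjusted over the list alone, those counts were 7 and 11, 11 and 14, 5 and 13, 4 and 1, 13 and 8, and 15 and 8. Markers of other cell types changed little as groups, with 0 up and 2 down of 10 for other islet endocrine cells, 2 and 1 of 18 for leukocytes, 4 and 1 of 16 for fibroblasts, 2 and 2 of 11 for endothelium and 5 and 3 of 19 for exocrine and ductal cells (the same counts adjusted over the list alone, adjusted p = 0.518, 0.527, 0.388, 0.859 and 0.527). Cd74 in the leukocyte list, Vim in the fibroblast list (2.08 ± 0.15) and Muc1 in the ductal list (2.09) were the marker genes that rose furthest in their lists.

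At 12 h of cytokines the interferon and NF-κB programmes were still up, while part of the ER-stress response had come down again. The cholesterol list, low at 6 h, was not called as a group (4 up and 5 down of 20, adjusted p = 0.987), and its level in untreated cells had dropped in the meantime. Nkx6-1 and Mafa stayed low. Of 14217 genes, 6528 changed (2271 up, 4257 down), 649 of them rising and 464 falling by at least 2-fold, and across genes the changes at 6 and 12 h correlated with Pearson r = 0.830 and Spearman r = 0.647, although genes are not independent replicates.

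Cxcl10 reached 9.40 ± 0.47 above untreated cells (13.49 against 4.09, adjusted p = 6.1e-13), Irf1 5.08 ± 0.11 (13.31 against 8.23) and Rsad2 8.56. Interferon targets again had 40 up and 0 down of 41 (40 and 0 adjusted over the list alone, median 5.35, adjusted p = 2.3e-46) and antigen-processing genes 19 up and 1 down of 22 (20 and 1 adjusted over the list alone, median 2.49, adjusted p = 8.17e-22). Socs1 rose by 4.13 ± 0.20 (adjusted p = 3.72e-13), though only 1 of its 2 probe sets moved in that direction, and Jak2 by 2.23 ± 0.14. JAK-STAT components counted 15 up and 7 down of 34 (15 and 7 adjusted over the list alone, median 0.23, adjusted p = 0.000242). Among NF-κB targets, Cxcl1 rose by 8.73 ± 0.23, Icam1 by 7.15 ± 0.18, Cd40 by 6.65 ± 0.18 and Nfkbia by 3.29 ± 0.08. Of the list, 27 of 34 were up and 0 down (27 and 0 adjusted over the list alone, median 2.42, adjusted p = 1.99e-22). Chemokines and cytokine ligands had 21 up and 2 down of 29 (22 and 2 adjusted over the list alone, median 1.46, adjusted p = 7.72e-15), and IL-1 and TNF receptor components 13 up and 4 down of 27 (15 and 4 adjusted over the list alone, median 0.25, adjusted p = 0.000129, and adjusted p = 0.0584 with an estimated correlation). Nos2 again did not move, at 6.15 with cytokines and 6.17 without (change −0.02 ± 0.11, adjusted p = 0.928).

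Ddit3 remained up by 1.53 ± 0.10 (9.32 against 7.79, adjusted p = 9.74e-11) and Atf3 by 3.98 ± 0.19. But Hspa5 was now lower, by 0.25 ± 0.06 (13.11 against 13.36, adjusted p = 0.00116). Untreated cells had read 13.06 for Hspa5 at 6 h, so part of its turn lies in the control. The unfolded-protein-response list as a whole had 12 up and 20 down of 43 (13 and 21 adjusted over the list alone, adjusted p = 0.86), with a median of −0.16 but a mean of 0.09. Tnfsf10 had risen further, to 4.99 ± 0.18, with Casp4 at 4.54 and Fas at 3.53 ± 0.11. Apoptosis genes counted 18 up and 8 down of 39 (19 and 8 adjusted over the list alone, median 0.32, adjusted p = 4.05e-05). Cdkn1a was up by 2.54 ± 0.21. The p53 targets counted 7 up and 3 down of 17 (7 and 3 adjusted over the list alone, median 0.10, adjusted p = 0.0496, and adjusted p = 0.066 with an estimated correlation). Immediate early genes rose in 14 and fell in 8 of 32 (14 and 8 adjusted over the list alone, median 0.24, adjusted p = 0.00219). Ubiquitin and proteasome genes rose in 15 and fell in 4 of 31 (16 and 5 adjusted over the list alone, median 0.16, adjusted p = 0.00036).

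Nkx6-1 fell by 1.76 ± 0.11 at 12 h (adjusted p = 3.87e-11), Nkx2-2 by 1.13 ± 0.17, the incretin receptor gene Gipr by 1.24 ± 0.11 and Mafa by 0.98 ± 0.07, and the glucose transporter gene Slc2a2 by 0.29 ± 0.06. Pdx1 was back at the untreated level (0.07, adjusted p = 0.541), and Ins1 (−0.01, adjusted p = 0.859) and Ins2 (−0.05, adjusted p = 0.505) did not differ. The identity list counted 16 down and 3 up of 34 (16 and 3 adjusted over the list alone, median −0.15, adjusted p = 0.0463, and adjusted p = 0.216 with an estimated correlation). Cell-cycle genes were still down, 30 against 5 up of 43 (31 and 5 adjusted over the list alone, median −0.33, adjusted p = 0.00119), with Cdkn2c at −1.16, and respiratory-chain genes had 27 down and 0 up of 43 (30 and 1 adjusted over the list alone, median −0.18, adjusted p = 0.00569, and adjusted p = 0.419 with an estimated correlation). In cholesterol synthesis only 4 genes were up and 5 down of 20 (4 and 5 adjusted over the list alone, median −0.02, adjusted p = 0.987). Slc15a2 (−3.32 ± 0.13), Pdzrn3 (−3.29 ± 0.10) and Mertk (−3.15), a receptor gene for dying-cell uptake, showed the deepest falls, and Usp9x was lower by 0.36 ± 0.08 (adjusted p = 0.000557).

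**Figure D1:**
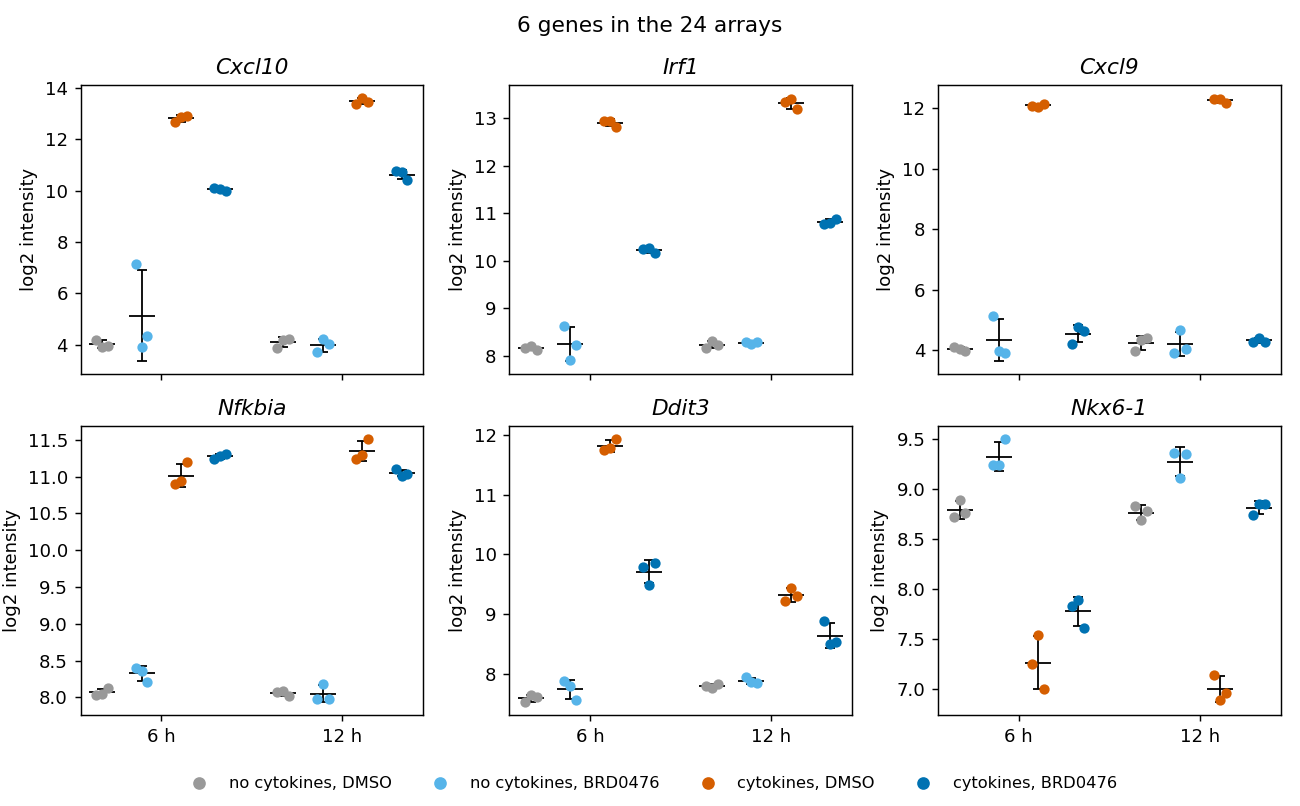
Log2 intensity of 6 genes in each of the 24 arrays, with the mean and standard deviation of each group of 3. Cxcl9 returns to near the untreated level when BRD0476 is given with the cytokines, Nfkbia does not, and a single array of the 6 h BRD0476 group without cytokines stands above its replicates for Cxcl10.

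Adding BRD0476 to the cytokines for 6 h pulled the interferon programme down. Cxcl9 fell back to near its untreated level and every interferon target that changed went lower. NF-κB targets were lowered less, ER-stress factors fell, and cholesterol, cell-cycle and respiratory-chain genes that cytokines had lowered were higher with the compound (for the last, adjusted p = 0.138 with an estimated correlation). Compared with cytokines and DMSO, 6261 genes changed (3506 up, 2755 down), and 294 rose and 502 fell by at least 2-fold.

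Cxcl9 dropped by 7.57 ± 0.23 (4.54 against 12.10, adjusted p = 1.4e-15), which is a lower bound as untreated cells read 4.03, Gbp4 by 5.56 ± 0.14, the complement gene C1s by 5.52 ± 0.12, Ifit2 by 5.19 ± 0.13 and Rsad2 by 4.77 ± 0.41. Irf1 fell by 2.68 ± 0.11 (10.23 against 12.91, adjusted p = 1.06e-13), as did Stat2 (−2.56 ± 0.13), Irf9 (−2.57) and Usp18, which restrains interferon receptors (−2.90). Cxcl10 fell by 2.77 ± 0.47 (10.05 against 12.82, adjusted p = 5.56e-05) and so kept much of its rise on the log2 scale. In linear intensity most of the rise was lost. Of 41 interferon targets, 38 fell and 0 rose (39 and 0 adjusted over the list alone, median −2.19, adjusted p = 3.41e-29). Tap1 fell by 2.95 ± 0.09 and Psmb9 changed by −1.60. Antigen-processing genes had 18 down and 1 up of 22 (18 and 1 adjusted over the list alone, median −0.94, adjusted p = 6.67e-13). Jak2 transcripts fell to 7.64 from 8.84 (adjusted p = 3.21e-07) and Socs1 changed by −1.66 ± 0.20. JAK-STAT components counted 14 down and 4 up of 34 (15 and 4 adjusted over the list alone, median −0.18, adjusted p = 0.00655).

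Within the NF-κB list the genes split. Icam1 fell by 1.75 ± 0.18 (adjusted p = 1.02e-07), with Il15 at −2.62 ± 0.12 and Sod2 at −0.56 ± 0.08, while Nfkbiz rose by 1.81 ± 0.13 (adjusted p = 2.12e-10; 1 of its 2 probe sets in that direction). Nfkbia rose by 0.26 ± 0.08 (11.28 against 11.01, adjusted p = 0.0121), and that call is lost without replicate 1 of the 6 h cytokine and DMSO group (0.21, adjusted p = 0.0738) or without its replicate 2 (0.23, adjusted p = 0.0545), or with only the 6 arrays compared (adjusted p = 0.0585). The list had 19 down and 4 up of 34 (20 and 4 adjusted over the list alone, median −0.42, adjusted p = 0.000194). Chemokines and cytokine ligands counted 13 down and 4 up of 29 (13 and 4 adjusted over the list alone, median −0.23, adjusted p = 0.000876), with Ccl5 at −2.73 ± 0.17, and IL-1 and TNF receptor components 13 down and 4 up of 27 (14 and 4 adjusted over the list alone, median −0.27, adjusted p = 0.00873, and adjusted p = 0.206 with an estimated correlation).

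The stress factors Atf3 (−2.40 ± 0.19), Ddit3 (−2.11 ± 0.10; 9.71 against 11.82, adjusted p = 1.46e-12) and Trib3 (−1.78) fell with the compound, and Hspa5 did not change (0.06, adjusted p = 0.406). The unfolded-protein-response list had 13 up and 17 down of 43 (13 and 17 adjusted over the list alone, median −0.13, adjusted p = 0.0534). Casp4 (−2.18), Casp12 (−2.32) and Tnfsf10 (−2.42) fell, and apoptosis genes counted 18 down and 9 up of 39 (18 and 9 adjusted over the list alone, median −0.15, adjusted p = 0.0335). Cdkn1a fell by 1.71 and Bbc3, which encodes the death factor PUMA, by 1.53, with 12 of 17 p53 targets down and 3 up (12 and 3 adjusted over the list alone, median −0.45, adjusted p = 0.00115).

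Genes lowered by cytokines moved up. Cholesterol synthesis had 15 up and 0 down of 20 (15 and 0 adjusted over the list alone, median 0.51, adjusted p = 1.89e-07), with Acat2 at 1.28 ± 0.10 and Stard4 at 1.10. Cell-cycle genes counted 28 up and 4 down of 43 (29 and 4 adjusted over the list alone, median 0.34, adjusted p = 2.9e-06), Cdkn2c at 1.25 among them. Respiratory-chain genes had 31 up and 1 down of 43 (33 and 1 adjusted over the list alone, median 0.28, adjusted p = 4.24e-07, and adjusted p = 0.138 with an estimated correlation), with Ndufa4 at 0.82 ± 0.05. Elovl6 rose by 2.26 ± 0.10 and Fasn by 1.23, and the quinone reductase gene Nqo1 by 1.93 ± 0.12 (adjusted p = 6.09e-11). The largest rises were C2cd4a, an islet gene, at 3.15 ± 0.13, Eeig2 at 2.99 ± 0.06 and Nptx1 at 2.77 ± 0.09. Mafa rose by 0.70 ± 0.07 (adjusted p = 2.68e-08), Pdx1 by 0.66 ± 0.08, Slc2a2 by 0.35 ± 0.06 and Ins2 by 0.23 ± 0.06, but Ins1 did not differ (0.07, adjusted p = 0.285). Not all of this need be a reversal, as Nqo1 was among the largest rises with BRD0476 alone at 6 h. Pdx1 also changed by 0.35 with BRD0476 alone at 6 h. That Pdx1 call is lost with only the arrays compared (adjusted p = 0.223). The Pdx1 interaction term of 0.31 at 6 h lost its call with a replicate block (adjusted p = 0.0628), among other alternatives. Usp9x rose by 0.92 ± 0.08 (adjusted p = 3.6e-09), about as far as cytokines had lowered it, and Nos2 stayed flat (0.07, adjusted p = 0.661).

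At 12 h BRD0476 still held the interferon programme down, and chemokine, apoptosis and NF-κB lists were lower as well. The chaperone gene Hspa5 and Nkx6-1 stood higher with the compound. Fewer genes changed than at 6 h: 3827, with 2323 up and 1504 down, of which 121 rose and 328 fell by at least 2-fold. With only the arrays compared the count was 2379 (1310 up, 1069 down). Across genes the BRD0476 effect at 6 and 12 h correlated with Pearson r = 0.636 and Spearman r = 0.451.

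Cxcl9 was lower by 7.95 ± 0.23 (4.32 against 12.27, adjusted p = 1.05e-15), C1s by 5.39, the macrophage-type pore gene Mpeg1 by 5.23 ± 0.12 and Gbp4 by 4.75. Irf1 fell to 10.81 from 13.31 (adjusted p = 4.41e-13), and Cxcl10 (−2.86 ± 0.47) and Stat2 (−1.93) fell with it. Interferon targets counted 40 down and 0 up of 41 (41 and 0 adjusted over the list alone, median −1.63, adjusted p = 7.32e-45), and antigen-processing genes 18 down and 0 up of 22 (18 and 0 adjusted over the list alone, median −0.94, adjusted p = 4.35e-19), with Tap1 at −2.35. Jak2 was lower by 1.60 ± 0.14 (adjusted p = 1.05e-08) and Socs1 by 3.50 ± 0.20 (1 of 2 probe sets in that direction), with JAK-STAT components 11 down and 4 up of 34 (11 and 4 adjusted over the list alone, median −0.16, adjusted p = 0.000368).

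Chemokine genes Ccl2 and Cxcl2 fell by 2.32 ± 0.13 and 2.23 ± 0.19, and their list had 15 down and 0 up of 29 (16 and 0 adjusted over the list alone, median −0.61, adjusted p = 8.98e-13). NF-κB targets counted 18 down and 1 up of 34 (19 and 1 adjusted over the list alone, median −0.42, adjusted p = 2.03e-09). Nfkbia fell by 0.30 ± 0.08 (adjusted p = 0.00865), but the call is lost without replicate 3 of the 12 h cytokine and DMSO group (−0.22, adjusted p = 0.0634) or with only the 6 arrays compared (adjusted p = 0.0684). Icam1 fell by 0.60 ± 0.18 (adjusted p = 0.0174), a call lost without replicate 1 (−0.56, adjusted p = 0.0562) or replicate 2 (−0.51, adjusted p = 0.0808) of that group, or without replicate 1 of the 12 h cytokine and BRD0476 group (−0.58, adjusted p = 0.0545). IL-1 and TNF receptor components had 10 down and 0 up of 27 (10 and 1 adjusted over the list alone, median −0.17, adjusted p = 0.00027, and adjusted p = 0.0719 with an estimated correlation). Immediate early genes had 11 down and 5 up of 32 (11 and 6 adjusted over the list alone, median −0.12, adjusted p = 0.00244). For ubiquitin and proteasome genes, 12 down and 4 up of 31 (12 and 4 adjusted over the list alone), the median of 0.02 and the mean of −0.18 differ in sign, with adjusted p = 0.0351 downward, and adjusted p = 0.18 with an estimated correlation.

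Death and stress genes also shifted. Tnfsf10 fell by 3.12 ± 0.18 (adjusted p = 1.87e-11), Casp12 changed by −2.26 and Casp4 by −1.73, and apoptosis genes counted 17 down and 4 up of 39 (17 and 4 adjusted over the list alone, median −0.18, adjusted p = 1.1e-06). Atf3 fell by 3.35 ± 0.19 and Ddit3 by 0.69 ± 0.10, whereas Hspa5 rose by 0.32 ± 0.06 (adjusted p = 0.000239) and Dnajb9, an ER co-chaperone gene, by 0.72 ± 0.14. The unfolded-protein-response list counted 22 up and 5 down of 43 (22 and 5 adjusted over the list alone, median 0.23, adjusted p = 0.00599, and adjusted p = 0.0545 with an estimated correlation). Cholesterol genes had 10 up and 0 down of 20 (11 and 1 adjusted over the list alone, median 0.28, adjusted p = 0.000782, and adjusted p = 0.0545 with an estimated correlation), with Pmvk at 0.69 and Insig1 at 0.59.

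Nkx6-1 stood at 8.81, close to its level in untreated cells but under the 9.27 of BRD0476 alone, and 1.81 ± 0.11 above cytokines with DMSO (adjusted p = 1.03e-10), and Nkx2-2 rose by 1.18 ± 0.17 and Mafa by 0.83 ± 0.07. The identity list had 8 up and 1 down of 34 (8 and 1 adjusted over the list alone, median 0.08, adjusted p = 0.0342, and adjusted p = 0.177 with an estimated correlation), and Ins1 (0.02, adjusted p = 0.881) and Ins2 (0.04, adjusted p = 0.695) stayed where they were. Pdzrn3 (3.08 ± 0.10), Mest (3.08 ± 0.21), C2cd4a (2.78) and the nuclear receptor gene Nr4a1 (2.45 ± 0.16) rose furthest. Nr4a1 was also among the largest rises with BRD0476 alone at 12 h, so its rise need not be a reversal. Glycolytic genes Pfkfb3 (−2.58 ± 0.08; 2 of its 3 probe sets in that direction), Pfkp (−1.91) and Aldoc (−1.54) fell, but glycolysis as a list was not called, with 9 up and 4 down of 28 (11 and 4 adjusted over the list alone, median 0.16, mean −0.02, adjusted p = 0.537). Usp9x no longer differed (0.10, adjusted p = 0.382), nor did Nos2 (−0.02, adjusted p = 0.911).

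**Figure D2:**
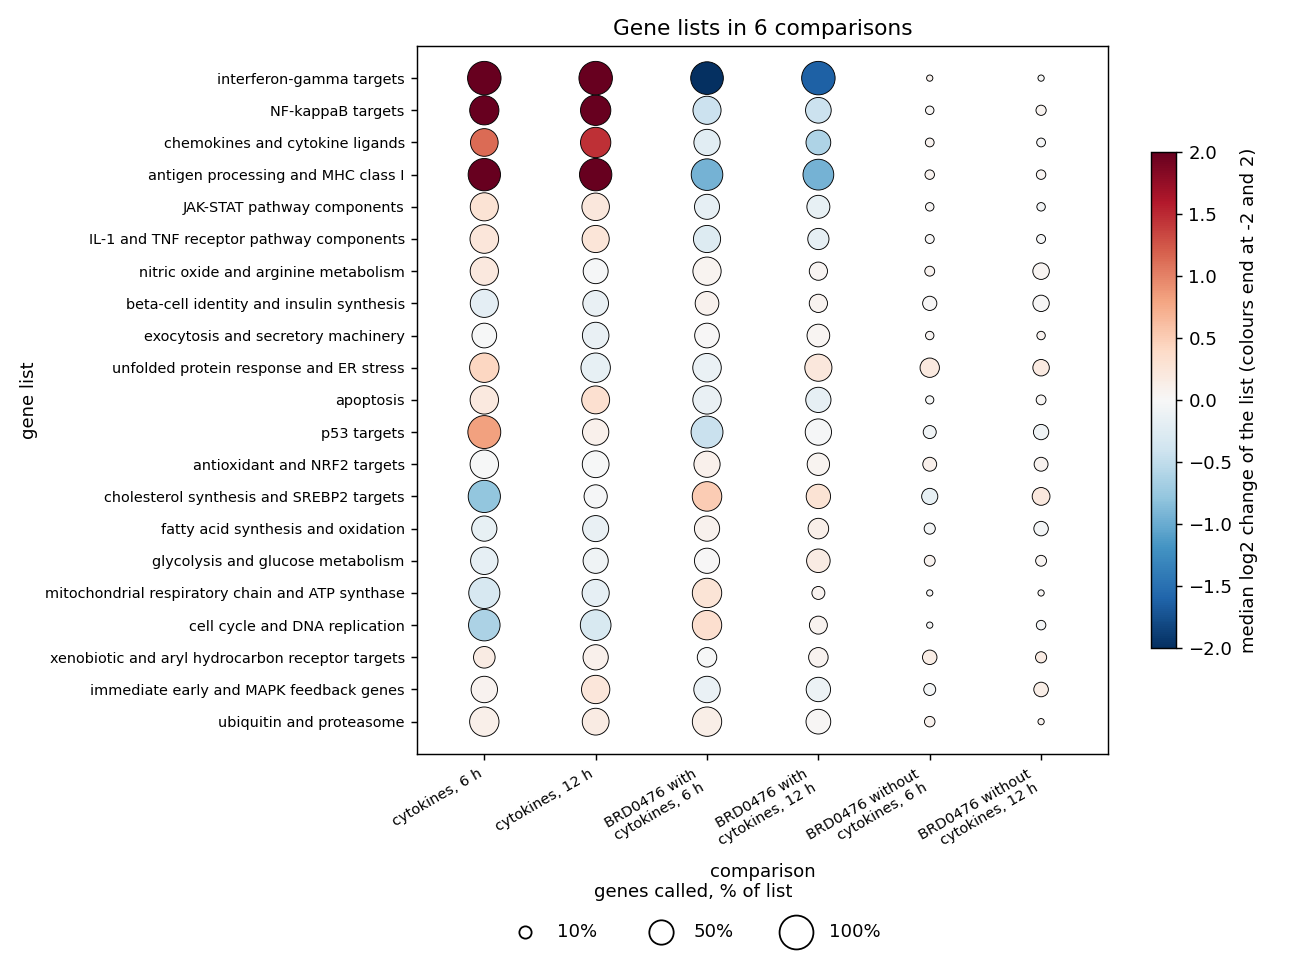
Median log2 change of each gene list in 6 comparisons, with the share of its genes called given by the size of the circle. The effects of BRD0476 are wide with cytokines and smaller without them.

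Without cytokines BRD0476 moved few genes, and by small amounts. It raised genes of the unfolded protein response and of the antioxidant response, and it moved cholesterol synthesis down at 6 h and up at 12 h, the latter against a control that had itself dropped. No interferon target was called at 6 h, though the list median was 0.09 (adjusted p = 0.0258, and adjusted p = 0.431 with an estimated correlation), and the insulin genes were not called. The antioxidant list has adjusted p = 0.051 at 6 h and 0.0991 at 12 h with an estimated correlation. At 6 h 502 genes changed (239 up, 263 down), 3 rising and 5 falling by at least 2-fold. At 12 h 663 changed (287 up, 376 down), 12 rising and 4 falling that far. These counts shrink to between 286 and 399 and between 360 and 431 when any single array of the comparison is left out. With only the arrays compared the 6 h count was 108, and with array weights the counts were 1123 and 1929. The effects at 6 and 12 h correlated with Pearson r = 0.597 and Spearman r = 0.518.

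At 6 h the largest rises were Pcp4l1 (1.19 ± 0.12, adjusted p = 6.58e-06), the GDNF receptor gene Gfra1 (1.04 ± 0.13) and Nqo1 (1.04 ± 0.12), and Mpv17l (−1.81 ± 0.17), Cyp4a8 (−1.27) and the lipase gene Lpl (−1.18 ± 0.10, adjusted p = 3.48e-07) fell most. Chac1, a glutathione-degrading target of ATF4, rose by 0.64 ± 0.10 (adjusted p = 0.000636) and Nupr1 by 0.41 ± 0.06, a call lost with only the 6 arrays compared (adjusted p = 0.0613). The unfolded-protein-response list had 13 up and 0 down of 43 (18 and 0 adjusted over the list alone, median 0.20, adjusted p = 2.02e-14). Hmox1 rose by 0.54 ± 0.08, with antioxidant genes 5 up and 0 down of 36 (8 and 0 adjusted over the list alone, median 0.10, adjusted p = 0.000477, and adjusted p = 0.051 with an estimated correlation) and xenobiotic targets 2 up and 0 down of 13 (3 and 0 adjusted over the list alone, median 0.15, adjusted p = 0.0121). Cholesterol genes had 4 down and 0 up of 20 (10 and 0 adjusted over the list alone, median −0.16, adjusted p = 2.51e-06), with Msmo1 at −0.45 ± 0.07 and Sqle at −0.38 ± 0.06, the latter not called with only the 6 arrays compared (adjusted p = 0.0728). Ubiquitin and proteasome genes had 2 up and 0 down of 31 (3 and 0 adjusted over the list alone, median 0.09, adjusted p = 0.000244).

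No interferon target was called by limma at 6 h, with 0 up and 0 down of 41 (0 and 0 adjusted over the list alone, 7 at an unadjusted p under 0.05), yet the list median was 0.09 (adjusted p = 0.0258, and adjusted p = 0.431 with an estimated correlation). Replicate 1 of the 6 h BRD0476 group without cytokines weighs on that: Cxcl10 read 7.16 there against 3.90 and 4.33 in replicates 2 and 3, its change of 1.12 ± 0.47 was not called (adjusted p = 0.247), and without that array the Cxcl10 change is 0.11, the list median 0.03 and 1 target is called. Without replicate 2 instead, Cxcl10 would be called (1.74, adjusted p = 0.0455). Irf1 (0.08, adjusted p = 0.805), Jak2 (0.05, adjusted p = 0.928), Usp9x (0.03, adjusted p = 0.915), Nos2 (0.19, adjusted p = 0.433), Ddit3 (0.15, adjusted p = 0.553), Ins1 (−0.03, adjusted p = 0.871) and Ins2 (0.01, adjusted p = 0.98) did not differ. Relb rose by 0.78 ± 0.16 (adjusted p = 0.00609), a call lost with only the 6 arrays compared (adjusted p = 0.0613), and Pfkfb3 (−0.76 ± 0.08), Bcl2l11 (−0.68 ± 0.06) and Myc (−0.68 ± 0.07) fell.

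At 12 h Chac1 was higher by 1.66 ± 0.10 (8.76 against 7.10, adjusted p = 3.6e-09) and Slc7a11, the cystine carrier, by 1.21 ± 0.15. Trib3 was higher by 0.95 ± 0.12 and Atf4 by 0.83 ± 0.07 (adjusted p = 1.51e-07). These differences are measured against a control that had dropped. Chac1 went from 9.09 at 6 h to 7.10 at 12 h in DMSO, and from 9.73 to 8.76 with BRD0476. Slc7a11, Trib3 and Atf4 likewise read lower at 12 h than at 6 h with either. The unfolded-protein-response list had 9 up and 0 down of 43 (14 and 0 adjusted over the list alone, median 0.18, adjusted p = 6.13e-14). Lrrc39 (1.96 ± 0.17, adjusted p = 4.77e-07), Nr4a1 (1.49 ± 0.16) and Gfra1 (1.36) were among the largest rises, and the clock gene Bmal1 (−1.45 ± 0.19) and Mpv17l (−1.41) among the largest falls. Cholesterol genes now had 5 up and 0 down of 20 (9 and 0 adjusted over the list alone, median 0.21, adjusted p = 9.61e-08), with Fdps at 0.46 ± 0.06. Gadd45a fell by 0.84 ± 0.07 and Sesn1 by 0.60, and p53 targets had 3 down and 0 up of 17 (4 and 1 adjusted over the list alone, median −0.09, adjusted p = 0.00111). Antioxidant genes had 5 up and 0 down of 36 (8 and 0 adjusted over the list alone, median 0.08, adjusted p = 0.00154, and adjusted p = 0.0991 with an estimated correlation). Ubiquitin and proteasome genes had 0 called of 31 by limma (0 adjusted over the list alone, 5 at an unadjusted p under 0.05, median 0.08, adjusted p = 0.0335, and adjusted p = 0.25 with an estimated correlation). Nkx6-1 rose by 0.51 ± 0.11 (adjusted p = 0.0108), but the call is lost without DMSO replicate 2 (0.47, adjusted p = 0.0596) or BRD0476 replicate 1 (0.46, adjusted p = 0.0583) or 3 (0.47, adjusted p = 0.0565). Cells kept Ins1 (0.01, adjusted p = 0.949), Ins2 (−0.02, adjusted p = 0.938), Irf1 (0.04, adjusted p = 0.919), Jak2 (−0.02, adjusted p = 0.969) and Hspa5 (0.07, adjusted p = 0.678) unchanged.

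In the presence of BRD0476, cytokines still induced chemokine, interferon and NF-κB genes relative to BRD0476 alone, with smaller steps for interferon genes. The early activation marker Cd69 and the chemokine Cxcl1 rose far at both times, and Nkx6-1 still fell at 6 h. At 6 h 2973 genes changed (1458 up, 1515 down), with 296 rising and 50 falling by at least 2-fold, and at 12 h 3938 changed (1307 up, 2631 down), with 331 and 79. With array weights the 12 h count was 6304 (2282 up, 4022 down).

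At 6 h Cd69 rose by 7.89 ± 0.20 (adjusted p = 4.58e-17), Cxcl1 by 7.52 ± 0.23, Cxcl2 by 4.92, Cxcl10 by 4.92 ± 0.47 (5.93 without replicate 1 of the 6 h BRD0476 group without cytokines), Icam1 by 4.81 ± 0.18 and Nfkbia by 2.95 ± 0.08, but Irf1 by only 1.98 ± 0.11, and Socs1 was not called (0.08, adjusted p = 0.848). Interferon targets had 30 up and 0 down of 41 (33 and 0 adjusted over the list alone, median 1.72, adjusted p = 4.84e-35) and NF-κB targets 22 up and 0 down of 34 (22 and 0 adjusted over the list alone, median 1.62, adjusted p = 1.5e-25). Cell-cycle genes had 23 down and 0 up of 43 (23 and 0 adjusted over the list alone, median −0.26, adjusted p = 1.65e-08). Glycolysis genes had 11 down and 2 up of 28 (13 and 2 adjusted over the list alone, median −0.24, adjusted p = 0.0015, and adjusted p = 0.133 with an estimated correlation). Nkx6-1 fell by 1.55 ± 0.11 (7.78 against 9.32, adjusted p = 1.18e-09), and the receptor genes Adora2b and Sstr2 fell by 2.13 ± 0.09 and 1.77 ± 0.20. At 12 h Cd69 rose by 7.69, Cxcl1 by 7.60 ± 0.23, Icam1 by 6.81 ± 0.18 (adjusted p = 7.95e-17), Cxcl10 by 6.66 ± 0.47 and Irf1 by 2.54 ± 0.11. Interferon targets had 32 up and 0 down (34 and 0 adjusted over the list alone, median 2.60, adjusted p = 3.32e-46), and NF-κB targets 22 up and 0 down (23 and 0 adjusted over the list alone, median 1.58, adjusted p = 2.36e-28). Apoptosis genes had 9 up and 7 down of 39 (9 and 7 adjusted over the list alone), with a median of −0.01 against a mean of 0.35 and adjusted p = 0.0301 upward.

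The share of the cytokine response left with BRD0476 is the slope of the response with the compound on the response with DMSO, over genes chosen at the other time point. Both responses are log2 changes, so the share does not give the part of the linear intensity that was kept. It was 0.483 at 6 h over 1113 genes (0.468 to 0.50 leaving out single arrays) and 0.573 at 12 h over 1604 genes (0.565 to 0.581). By this slope, genes that cytokines raised kept more (0.502 and 0.588) than genes they lowered (0.376 and 0.483). By the median of ratios the order turns at 6 h (0.364 against 0.381) and the gap narrows at 12 h (0.561 against 0.514). NF-κB targets kept 0.824 at 6 h over 22 genes and 0.792 at 12 h over 23, whereas interferon targets kept 0.475 and 0.615 over 38 genes each. Antigen-processing genes kept 0.540 and 0.580, and unfolded-protein-response genes 0.356 over 7 genes and 0.144 over 11. For the latter the median of ratios was 0.190 at 6 h and 0.232 at 12 h, so the order in time depends on the measure. Of 649 raised genes chosen for 6 h, 514 were called lower with BRD0476 and 33 higher, and of 464 lowered genes 346 were called higher and 31 lower. At 12 h the corresponding counts were 488 and 58 of 887, and 385 and 28 of 717.

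**Figure D3:**
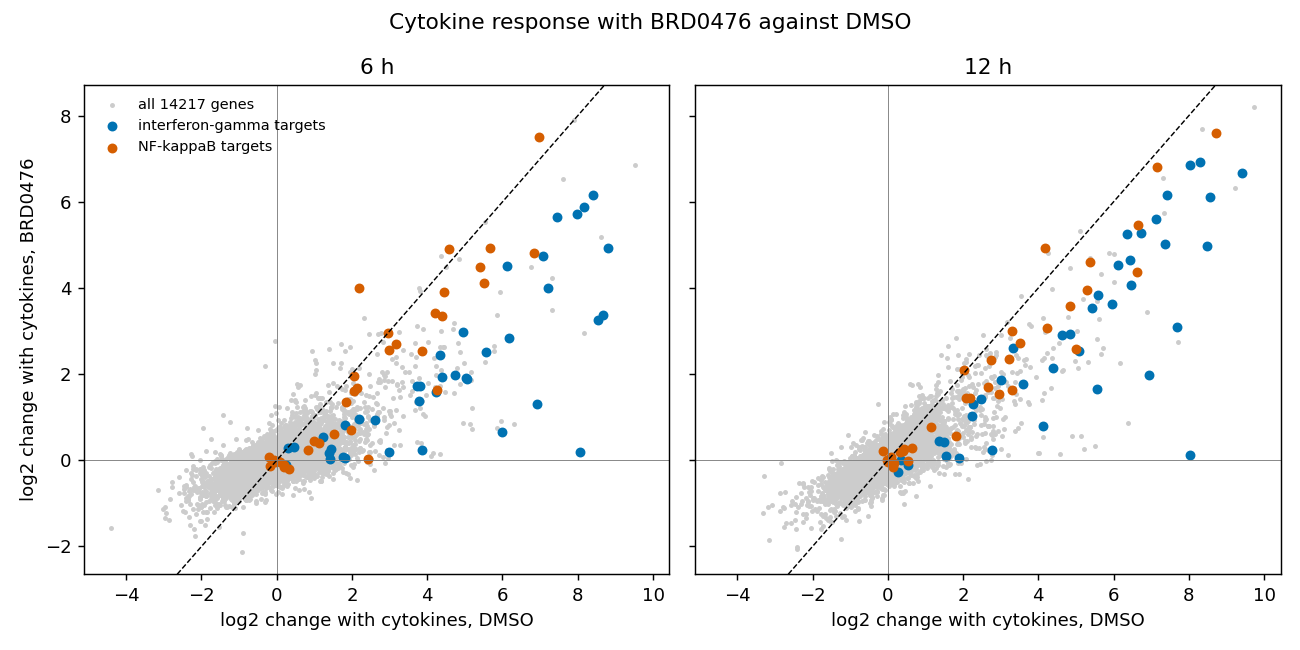
Log2 change with cytokines in BRD0476 against the change in DMSO for 14217 genes at 6 and 12 h, with both target lists in colour. Among genes that rose with cytokines in DMSO, points under the dashed line of equal response had a smaller induction with BRD0476. Among genes that fell, points above the line had a smaller fall.

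Interaction terms ask whether the compound changes the cytokine response beyond what it does alone. Interferon and antigen-presentation genes carried large negative terms at both times. NF-κB targets carried smaller ones, and the term of Nfkbia was not called at either time. At 6 h 4717 genes had a term that passed (2666 up, 2051 down), 344 and 507 of them of at least 1 on the log2 scale, and at 12 h 2170 did (1191 up, 979 down), with 115 and 328. Effects of BRD0476 with and without cytokines hardly correlated across genes (Pearson r = 0.0221 at 6 h and 0.184 at 12 h).

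At 6 h the terms were −7.87 ± 0.33 for Cxcl9 (adjusted p = 5.04e-13), −5.61 ± 0.20 for Gbp4, −2.76 ± 0.16 for Irf1, −3.25 ± 0.13 for Tap1, −2.03 ± 0.26 for Icam1, −2.26 ± 0.15 for Ddit3 and −1.25 ± 0.19 for Jak2, against 0.00 ± 0.12 for Nfkbia (adjusted p = 0.987). Interferon targets had 38 negative and 0 positive of 41 (38 and 0 adjusted over the list alone, median −2.26, adjusted p = 2.47e-33), NF-κB targets 18 and 1 of 34 (19 and 1 adjusted over the list alone, median −0.47, adjusted p = 7.58e-05), and unfolded-protein-response genes 21 and 3 of 43 (22 and 4 adjusted over the list alone, median −0.34, adjusted p = 8.73e-06). Cholesterol genes had 17 positive and 0 negative of 20 (18 and 0 adjusted over the list alone, median 0.75, adjusted p = 6.65e-11), with Acat2 at 1.58 ± 0.14. Cell-cycle genes had 27 and 4 of 43 (27 and 4 adjusted over the list alone, median 0.35, adjusted p = 3.81e-07). Mafa (0.46 ± 0.10, adjusted p = 0.000647) and Usp9x (0.89 ± 0.11) were positive. At 12 h Cxcl9 stood at −7.92 ± 0.33, Irf1 at −2.54 ± 0.16, Atf3 at −3.81 ± 0.26, Jak2 at −1.58 ± 0.19, Nkx6-1 at 1.30 ± 0.16 (adjusted p = 4.28e-06) and Mafa at 0.75 ± 0.10, while Icam1 (−0.34 ± 0.26, adjusted p = 0.486) and Nfkbia (−0.29 ± 0.12, adjusted p = 0.109) did not pass. Interferon targets had 37 negative and 0 positive of 41 (41 and 0 adjusted over the list alone, median −1.72, adjusted p = 8.19e-49), and apoptosis genes 14 and 0 of 39 (15 and 3 adjusted over the list alone, median −0.26, adjusted p = 2.41e-06).

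Between 6 and 12 h the cytokine response itself shifted. Ccl2, Egr1 and Tnf gained, ER-stress genes lost much of their induction, and the gap to untreated cells narrowed for cholesterol and cell-cycle genes. The clock output gene Dbp turned from a rise of 1.83 at 6 h to a change of −0.90 at 12 h. The time term of the cytokine response passed in 4089 genes (1681 up, 2408 down).

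Ccl2 gained 3.03 ± 0.18 (adjusted p = 1e-10), Egr1 2.64 ± 0.16, Tnf 1.95 ± 0.25 and Socs1 2.37 ± 0.29 (1 of 2 probe sets in that direction). Nr1d1, the clock repressor REV-ERB alpha, changed by −3.78 ± 0.35 (adjusted p = 7.61e-08), the clock output gene Dbp by −2.73 ± 0.14 and Ddit3 by −2.70 ± 0.15 (adjusted p = 3.91e-11). Unfolded-protein-response genes had 26 down and 2 up of 43 (29 and 3 adjusted over the list alone, median −0.39, adjusted p = 5.84e-10), Dnajb9 at −2.07 ± 0.20 and Hspa5 at −0.61 ± 0.08 among them. Cholesterol genes had 18 up and 0 down of 20 (18 and 0 adjusted over the list alone, median 0.79, adjusted p = 5.11e-14), with Acat2 at 1.44 ± 0.14, and cell-cycle genes 27 and 2 of 43 (29 and 3 adjusted over the list alone, median 0.35, adjusted p = 5.84e-10), with Plk1 at 1.26 ± 0.08. Chemokines gained in 11 and lost in 1 of 29 (14 and 1 adjusted over the list alone, median 0.40, adjusted p = 0.000202). Pdx1 regained 0.63 ± 0.11 (adjusted p = 0.000226) and Usp9x 0.55 ± 0.11.

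The effect of BRD0476 on cytokine-treated cells also changed with time, in 3559 genes (1687 up, 1872 down). Nr1d1 (4.10 ± 0.35, adjusted p = 5.03e-08), Dbp (2.94 ± 0.14) and Bhlhe41 (2.55 ± 0.11) had the opposite sign to their cytokine time terms. Nfkbiz (−2.82 ± 0.18, adjusted p = 6.59e-10), Egr1 (−2.72 ± 0.16) and Tnf (−2.54 ± 0.25) went from higher towards lower. Nfkbia differed by −0.56 ± 0.12 (adjusted p = 0.00106), Icam1 by 1.14 ± 0.26, Nkx6-1 by 1.30 ± 0.16 and Usp9x by −0.82 ± 0.11. Unfolded-protein-response genes had 21 up and 3 down of 43 (23 and 3 adjusted over the list alone, median 0.33, adjusted p = 1.67e-06), and cell-cycle genes 23 down and 1 up of 43 (24 and 3 adjusted over the list alone, median −0.29, adjusted p = 1.59e-07). Cholesterol genes had 10 down and 0 up of 20 (11 and 0 adjusted over the list alone, median −0.32, adjusted p = 0.000118, and adjusted p = 0.065 with an estimated correlation).

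Untreated cells in DMSO drifted between 6 and 12 h in few genes, 238 in all (66 up, 172 down), but cholesterol synthesis was among them. The count is not stable: it was 132 to 279 without single arrays, 97 with only the arrays compared, 104 with a replicate block and 1545 with array weights, where 824 went up and 721 down. In that list 18 of 20 genes were lower at 12 h and 0 higher (19 and 0 adjusted over the list alone, median −0.63, adjusted p = 2.34e-61), with Fdft1 at −1.03 ± 0.10 (adjusted p = 1.37e-06) and Idi1 at −0.86 ± 0.09. Chac1 fell by 1.99 ± 0.10 (adjusted p = 1.19e-10), with Trib3 at −1.23 ± 0.12 and Nupr1 at −1.28 ± 0.06. The splicing genes Rsrp1 and Clk4 rose by 1.51 ± 0.09 and 0.89 ± 0.10. The mean of the cholesterol list was 9.91 in untreated cells at 6 h and 9.27 at 12 h, against 9.10 and 9.23 with cytokines, so most of the closing gap came from the untreated cells. Cell-cycle genes had 4 down and 0 up of 43 (10 and 0 adjusted over the list alone, median −0.06, adjusted p = 8.54e-06). Medians over all genes stayed within 0.1 of 0 in every comparison.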

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

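Of the tests in this part, the checks for degraded RNA and for an array of another group, the check for carried RNA, and the fit without both replicate 3 arrays were chosen after the result was seen, and the other splits, the matched lists and the exchanges were planned.

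The response moved with time in many genes. Counted here are genes named for the 6 h or 12 h comparisons, not those named only for the time terms, such as Dbp. Of 78 genes followed by name for cytokines in DMSO, 43 had effects that differed between 6 and 12 h, and 3 were called in opposite directions: Hspa5 (12 h minus 6 h: −0.61), Vldlr (−1.92) and Pfkfb3 (1.90). Of 72 followed for BRD0476 with cytokines, 51 differed, and 3 had opposite calls: Nfkbiz (−2.82), Nfkbia (−0.56) and Dnajb9 (1.82). The Nfkbia calls are the weak ones of these, since each is lost on leaving out a single array. For the others the cause was not tested, though Hspa5 also moved in untreated cells, from 13.06 at 6 h to 13.36 at 12 h.

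Probe sets without a single gene name were left out of the fit by gene. Fitted on their own, 3059 of 10216 were called with cytokines at 6 h and 2450 at 12 h, 2341 and 1163 for BRD0476 with cytokines, and 58 and 121 for BRD0476 alone. With cytokines at 6 h 971 rose and 2088 fell. They cannot be assigned to genes here, so the counts of changed genes leave this part of the array out.

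Replicate 3 of the cytokine and DMSO group stands apart from replicates 1 and 2 at both times. At 6 h 186 genes lie at least 1 from the mean of the others and at 12 h 201 do, against 0 to 81 in the other arrays. The 81 are in replicate 1 of the 12 h cytokine and BRD0476 group. That array also lies apart from its replicates on the fourth principal component (2.68 against −13.2 and −18.8). On the same component, replicate 3 of the 12 h cytokine and DMSO group lies at 25.5 against −2.11 and −4.24. In replicate 3 of the cytokine and DMSO groups, Scaf1 (−2.97 and −2.97), Pfkl (−2.66 and −2.50 at 6 and 12 h) and Ncdn are the lowest by the mean of both times. Degraded RNA would raise the 3' minus 5' signal of the actin and GAPDH controls, but the difference was −0.240 at 6 h and −0.00988 at 12 h. Those controls thus show no sign of it. The actin value also ranged from 1.77 to 2.33 within the 12 h cytokine and BRD0476 group, so these few controls do not exclude degraded RNA. An array of another treatment group would follow the cytokine response with a slope under −0.3. The slope was −0.0614, which excludes that. Over 8924 genes that no comparison without these groups calls, the deviations at 6 and 12 h correlated with r = 0.723. Pairs of a 6 h and a 12 h array within each of the other treatments gave −0.358 to 0.379. Both arrays may therefore share a source apart from the treatment, such as a common culture or handling batch. The labels do not say which. Pairs across treatments were not part of that range. At 12 h, arrays of different replicate number correlated at up to 0.525 between the cytokine groups with BRD0476 and with DMSO. The deviation may thus not be confined to replicate 3 of the cytokine and DMSO groups. Without both of these replicate 3 arrays, 7493 genes are called with cytokines at 6 h in place of 7345 and 6859 in place of 6528 at 12 h.

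NF-κB targets kept a larger share of the cytokine response than interferon targets. Interferon genes also rose further, so the size of the rise alone could give such a gap. Lists of other risen genes matched on the rise gave a median share of 0.449 at 6 h (0.328 to 0.584) and 0.516 at 12 h (0.388 to 0.666), while the NF-κB list had 0.798 and 0.726. It lay at percentile 100 and 99.84 of 10000 matched lists, which argues against size as the only cause. Exchanging members between both lists gave as large a gap in a share of 1e-04 at 6 h, the smallest such draws can give. At 12 h the share was 0.0095. Both kinds of draw treat genes as independent, although members of a list can move together. The percentiles and shares can then be too extreme, so chance membership is not excluded. Other differences between the lists, such as their levels in untreated cells, their timing and members they share with other lists, were not tested. Median shares of interferon targets were 0.407 and 0.605.

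Interferon genes stand higher in replicate 1 of the 6 h BRD0476 group without cytokines: the list mean is 6.03, against 5.55 in replicate 2, with Rsad2 at 6.65 against 4.26 and 4.23. Over 45 genes that rose by at least 5 with cytokines, the linear signal above untreated cells was set against that with cytokines and DMSO. In replicate 1 the median was 0.379% and the lower quartile 0.0682%, against medians of −0.0438% and −0.0125% in the other replicates. The upper quartile in replicate 1 was 0.728%. A small amount of RNA from a cytokine-treated sample could give this. The genes were chosen for rising with cytokines, so the check restates the observation and does not decide its cause. A source treated with BRD0476 as well is not decided: the share implied in 21 genes that BRD0476 lowers was 0.308 of that in 24 others (0.172% against 0.559%), between both bounds. Cxcl9 reads 5.13 in that array and 4.54 in the cytokine and BRD0476 group, which goes against such a source, but a single gene at so low a level excludes nothing. Trace exposure of that culture to cytokines is not decided either, as NF-κB and interferon genes imply similar shares (ratio 0.805, from 5 and 18 genes). Without this array the comparison calls 286 genes in place of 502.

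Other splits of the same arrays mix arrays of different groups. A real effect then widens the spread within each group and lowers the count. Low counts there therefore do not show what grouping like arrays by chance would give. For each comparison of 3 arrays against 3 there are only 10 splits, too few for a share under 0.05, and in each only 1 split, the real one, called as many genes. The highest other count was 1 for cytokines with DMSO at 6 h (real 7345), BRD0476 alone at 6 h (502) and untreated cells over time (238). It was 0 for cytokines with DMSO at 12 h (6528), BRD0476 with cytokines at 6 h (6261) and 12 h (3827), BRD0476 alone at 12 h (663), and cytokines with BRD0476 at 6 h (2973) and 12 h (3938). For interactions 100 splits were drawn, the real one included. As many genes came up in 3 for BRD0476 by cytokines at 6 h (highest other 4985, real 4717) and 4 at 12 h (2307 against 2170), both shares under 0.05. For the time terms it was 8 for cytokines (4296 against 4089) and 7 for BRD0476 (5887 against 3559), which are not under 0.05. All of the other splits that reached the real count (2, 3, 7 and 6) kept 1 side of the interaction as labelled and mixed only the other, so the whole effect of that side entered the term. With both sides mixed the highest counts were 0, 0, 5 and 382.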

How the results depend on the processing

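The fit without both replicate 3 arrays of the cytokine and DMSO groups was chosen after the result was seen, and all other alternatives in this part were planned.

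Counts of genes and shares of the response make 15 results with 287 alternatives, of which 257 kept the result and 30 moved it by over 1.5-fold for a count or beyond its standard error for a share. Fitting only the arrays compared gave 2379 genes for BRD0476 with cytokines at 12 h (3827 in the report), 108 for BRD0476 alone at 6 h (502) and 97 for untreated cells over time (238). Array weights gave 1123 for BRD0476 alone at 6 h, 1929 at 12 h (663), 6304 for cytokines with BRD0476 at 12 h (3938) and 1545 for untreated cells over time. The balance of directions can turn with scaling. With BRD0476 alone at 6 h 47.6% of calls were higher, but 55.3% with centred arrays and 52.0% with quantile normalization. For the 12 h interaction of BRD0476 and cytokines, 54.9% became 46.9% with centred arrays.

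Leaving out single arrays gave 286 to 399 genes for BRD0476 alone at 6 h, with the lowest counts without BRD0476 replicate 1 (286) and replicate 2 (297). At 12 h it gave 360 to 431, and each of the 6 arrays lowered the count by over 1.5-fold. Untreated cells over time gave 132 to 279, with low counts without 6 h replicate 1 (142) or any of the 12 h replicates (139, 132 and 147). Cytokines with DMSO ranged from 6834 to 7285 at 6 h and from 5769 to 6643 at 12 h, BRD0476 with cytokines from 5625 to 6300 and from 3286 to 3641, and cytokines with BRD0476 from 2461 to 2595 and from 3015 to 4275. Interactions ranged from 4224 to 5077 and 1837 to 2192 for BRD0476 by cytokines at 6 and 12 h, from 3578 to 4075 for time by cytokines and from 3075 to 4036 for time by BRD0476.

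The labels number replicates 1 to 3 in every group without saying whether equal numbers share a culture. In no comparison did all 3 same-number pairs correlate above 0.1. With a replicate block, untreated cells over time had 104 genes in place of 238, and no other count moved: cytokines with DMSO gave 7266 and 6360, BRD0476 with cytokines 6175 and 3668, and BRD0476 alone 425 and 560.

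The share of the response left at 6 h was 0.483. It became 0.519 over genes with a change of at least 2, 0.440 over genes chosen at the same time point, 0.372 as the median of ratios, 0.376 over genes that fell and 0.454 without both replicate 3 arrays, and single arrays gave 0.468 to 0.50. At 12 h the share of 0.573 became 0.599, 0.560 and 0.531 by the first of these choices, 0.588 over genes that rose and 0.483 over genes that fell, and single arrays gave 0.565 to 0.581.

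Single genes make 407 results, among them every gene value above, with 6847 alternatives: 6767 kept the call, 69 lost it, 11 gained one and 0 reversed. All changes fall in 28 results, most of them with BRD0476 alone. Fitting only the arrays compared ended the calls of Manf (adjusted p = 0.0650), Nupr1 (0.0613), Sqle (0.0728) and Relb (0.0613) with BRD0476 alone at 6 h, and of Slc7a11 in untreated cells over time (0.0719). Bcl2l11 with BRD0476 alone at 12 h went from a call to −0.08 (adjusted p = 0.628) with the mean of its probe sets.

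Gene lists make 338 results with 1352 alternatives: 1217 kept the call, 40 lost it, 93 gained one and 2 reversed. Of the 93, 89 come with fry, whose PValue tests whether a set's genes move one way, not against other genes. The reversed results are also from fry: cholesterol synthesis with cytokines at 12 h (adjusted p = 0.0360, downward) and leukocyte markers with cytokines and BRD0476 at 6 h (adjusted p = 0.00127, upward). Neither list was called by camera.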

Other observations

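Both gene lists in this part, clock genes and the arms of the unfolded protein response, were chosen after the result was seen, as were both exchange tests between the arms.

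As a list, genes of the circadian clock answered the cytokines in opposite ways at 6 and 12 h, though not every member did. Nr1d1, which encodes the repressor REV-ERB alpha, went from 5.17 in untreated cells to 9.26 with cytokines at 6 h and stood at 5.67 when BRD0476 was added. By 12 h it was at 5.43 with cytokines against 5.13 without, which is not called (adjusted p = 0.345) but is a called rise without both replicate 3 arrays of the cytokine and DMSO groups (0.59, adjusted p = 0.00416). Bmal1 went from 6.16 to 7.68 at 6 h and read 6.91 against 6.48 at 12 h. Dbp went from 8.50 to 10.33 at 6 h and to 8.52 with BRD0476, but at 12 h from 8.33 down to 7.43 and to 8.56 with the compound. Bhlhe41 followed the same course, 9.88 to 11.81 and 10.26 at 6 h, and 9.88 to 9.24 and 10.23 at 12 h. Of 18 clock genes measured, 12 rose and 1 fell with cytokines at 6 h (median 0.56, adjusted p = 0.000275) and 0 rose and 9 fell at 12 h (median −0.29, adjusted p = 0.0199). BRD0476 with cytokines gave 1 up and 11 down at 6 h (median −0.52, adjusted p = 2.15e-05) and 11 up and 2 down at 12 h (median 0.47, adjusted p = 0.000215). BRD0476 alone gave 1 up and 2 down at 6 h (median 0.04, adjusted p = 0.436) but 6 up and 2 down at 12 h (median 0.13, adjusted p = 0.000236), with Dbp at 0.50 and Bmal1 at −1.45. The rise with BRD0476 in cytokine-treated cells at 12 h is therefore not to be read as a reversal of the cytokine effect alone. Untreated cells showed 0 up and 0 down between 6 and 12 h by limma. Members were picked in part because they had moved, so these p-values are too small, and the cause was not tested.

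BRD0476 alone raised the unfolded-protein-response list, and its ATF4 and CHOP arm, which answers amino-acid shortage as well as ER stress, was set beside the arm of chaperones and degradation. The 15 genes of the first arm had a median of 0.28 at 6 h and 0.44 at 12 h, against 0.19 and 0.13 in 20 genes of the second. Exchanging members between the arms gave as large a difference in a share of 0.0422 at 6 h and of 1e-04 at 12 h, the smallest such draws can give. The arms were drawn after Chac1, Trib3 and Atf4 had been seen to rise, so that test decides nothing. With the members named for BRD0476 alone left out, 9 and 18 genes remain, with medians of 0.21 against 0.19 at 6 h (share 0.187) and of 0.39 against 0.13 at 12 h (share 1e-04, again the smallest). Whether the first arm rises more is thus open at 6 h. At 12 h it may do so, but the same arm drifted in untreated cells, with 0 up and 7 down between 6 and 12 h (median −0.27), so the rise is measured against a falling control. Protein-level readouts of ATF4 and of eIF2alpha phosphorylation would separate the arms directly.

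With cytokines at 6 h 14 genes of the ATF4 and CHOP arm rose and 0 fell (median 1.37, adjusted p = 8.84e-10), and chaperone and degradation genes had 8 up and 4 down (median 0.04, adjusted p = 0.285). The difference between the arms was not tested there. With cytokines at 6 h BRD0476 lowered 11 genes of the ATF4 and CHOP arm and raised 0 (median −0.90, adjusted p = 2.87e-08), but at 12 h it lowered 3 and raised 7 (median 0.23, adjusted p = 0.296). Members were picked in part because genes of this arm had moved, so these p-values are too small.

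Nos2 stayed near an intensity of 6 on the log2 scale in all 8 groups while Cxcl10, Icam1 and Sod2 rose. It is read by 1 probe set, and nothing else here measures nitric oxide, so whether the gene is silent in these cells or the probe set does not read its transcript was not tested.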
